A study of Ovis aries with 12 samples.

How the data were processed

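RNA sequencing libraries were prepared from total RNA of flash-frozen tissue, extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The labels give sheep as the organism. The deposited files hold raw read counts per gene, 1 file per library and 24616 genes in each, and the gene column carries cattle gene identifiers, per the file headers. The authors used Bowtie 0.12.2, per the submitters' processing notes, which name the cattle build bosTau8 for 7 libraries and no build for the 5 labelled ovary. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. If sheep reads were counted on cattle genes, genes that differ between the species could be undercounted, which was not tested, and reads shared between near-identical genes or overlapping genes cannot be told apart without the counting rules.

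The 12 libraries were put into the groups Co-L, Co-H, T-L and T-H by their titles, 3 in each. One file has a blank line, which was skipped, and in the file of T-H 3 the header runs into the first gene, whose count was read from that line. A sheep gene table was given for names, with an empty column for Ensembl identifiers, and 0 of the 24616 identifiers matched any of its entries. No gene could therefore be named, and the 43 gene lists fixed before the data were examined, the gene set tests planned on them and the planned check of tissue marker genes were not run. Coordinates were not used here.

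Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out with filterByExpr at a minimum count of 10, which kept 14839 genes, libraries were scaled by the trimmed mean of M values (TMM), and all 12 libraries entered a model with 1 mean per group and a shared estimate of the spread. The quasi-likelihood test was applied to 5 contrasts: T against Co, Co-H against Co-L, T-H against T-L, high against low fertility over both tissues, and the difference of the fertility contrasts between T and Co. P-values were adjusted by Benjamini-Hochberg within a contrast and called under 0.05. Group values are given as mean ± SD of TMM-scaled CPM. Only the genes found in a single tissue and the genes on in some libraries and off in others were picked on CPM of the unadjusted library total. Log2 CPM with a prior count of 2 was used for principal components and correlations. The model, the tests and the alternatives were chosen before the data were examined, unless a setting is said to be chosen later.

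The rule for named genes, set before the data were examined, took genes with a symbol, an adjusted p under 0.05, a mean of at least 2 CPM and full separation of the groups, ordered by log2 change. With no symbols, it was applied without that condition and limited to 2 genes in each direction. In contrasts with fewer than 10 called genes it took those with the smallest unadjusted p. For a gene with no counts in a tissue the fold was taken against a floor of 3 counts over the 6 libraries of that tissue. Genes called between the tissues at 8-fold or more formed a T-biased and a Co-biased class, which were chosen after the data were seen and tested for the fertility contrasts with camera in limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation.

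Replicates were compared by a chi-square test of their counts over genes. The statistic per degree of freedom was 19.0 to 143 over the 12 pairs within groups, so no pair agreed within sampling noise and each library counted as 1 replicate. Total counts of 9627378 to 17852552 per library set the precision. A count of 3 over the 6 libraries of a tissue corresponds to 0.0381 CPM in Co and 0.0358 CPM in T.

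The test was tested on simulated counts drawn from the means, library sizes and spread of these libraries, with 200 genes changed. The changed genes were taken only from those above a set mean count, and no simulated library was set apart from its group. Recovery of genes with few counts was therefore not measured. For Co-H against Co-L it recovered 20% of the genes changed 2-fold and 88.5% of those changed 4-fold. For T-H against T-L it recovered 30% and 91.5%, and for T against Co 75.5% and 95.5%. Between 3.80% and 6.98% of the calls were false.

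The alternatives were size factors by relative log expression (RLE) or upper quartile, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no count filter, a filter of at least 1 CPM in at least 3 libraries, only the 6 libraries of a tissue, the replicate number as a block, and leaving out each library in turn. Adjusted p under 0.1 and the settings without libraries that stood apart were chosen after the data were seen. Other splits of the libraries into groups of the same sizes were refitted in the same way, all 10 within a tissue, 60 drawn at random of 200 for the tissues and 100 drawn of 200 for fertility. The numbers drawn were settled after smaller draws had been seen.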

Results

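Gene expression was measured by RNA sequencing in 12 libraries from flash-frozen reproductive tissue that the labels give as sheep. The libraries formed 4 groups of 3, named Co-L, Co-H, T-L and T-H, where L and H stand for low and high fertility in the labels. All 6 T libraries were labelled endometrium, the inner lining of the uterus. Of the 6 Co libraries 5 were labelled ovary, and the library Co-H 3 was labelled corpus luteum, the progesterone-producing gland that forms in the ovary after ovulation. The file headers call all 6 Co libraries CL and all 6 T libraries Endo. The design text also names 6 control and 6 treatment samples without saying which they are. What Co and T stand for is not given in the sources used here, and any factor besides tissue that differed between them could not be separated from tissue. The labels speak of pooled samples and do not state that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

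The files held raw counts for 24616 genes under cattle gene identifiers. They do not pair those identifiers with gene names, and 0 of them matched the sheep gene table used here, so genes are given by identifier, with at most 2 higher and 2 lower genes per comparison. Total counts per library ranged from 12665680 to 17852552 in Co and from 9627378 to 13934369 in T. Between 15935 and 17156 genes had at least 1 count. In Co-H 2 and Co-H 3 17091 and 17014 genes did, against 15935 to 16609 in Co-H 1 and the Co-L libraries. The TMM scaling factors were 0.977 in Co-H 2 and 1.00 in Co-H 3, against 0.745 to 0.864 in Co-H 1 and the Co-L libraries. Whether this difference in composition bears on Co-H against Co-L was not tested. The most abundant gene of each library took 7.40% ± 0.81 of the counts in Co and 2.69% ± 1.24 in T (SD, n = 6 each). It was ENSBTAG00000043561 in every library except T-H 1, where it was ENSBTAG00000031160. Its share was 5.20% in T-H 1 and 1.90% to 2.41% in the other T libraries. The 10 most abundant genes took 18.2% ± 1.31 in Co and 9.48% ± 2.40 in T, with T-H 1 at 14.2%. For the shares of counts of single libraries given here, the 95% Wilson interval reaches at most 0.0219 percentage points to either side, which covers counting error only. After low-count genes were left out, 14839 genes were tested, and their levels are given in CPM, the count scaled to the total of the library after TMM adjustment.

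Tissue was the main difference between the libraries. The first principal component of log2 CPM held 75.0% of the variance and separated the 6 Co from the 6 T libraries. Pearson's r across genes was 0.732 to 0.802 between a Co and a T library, 0.899 to 0.982 between Co libraries and 0.945 to 0.979 between T libraries. On the second component, with 7.50% of the variance, Co-L 3 lay at 88.7 and the other Co libraries between −49.3 and 22.0. The T libraries lay between −7.87 and 8.91.

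**Figure D1:**
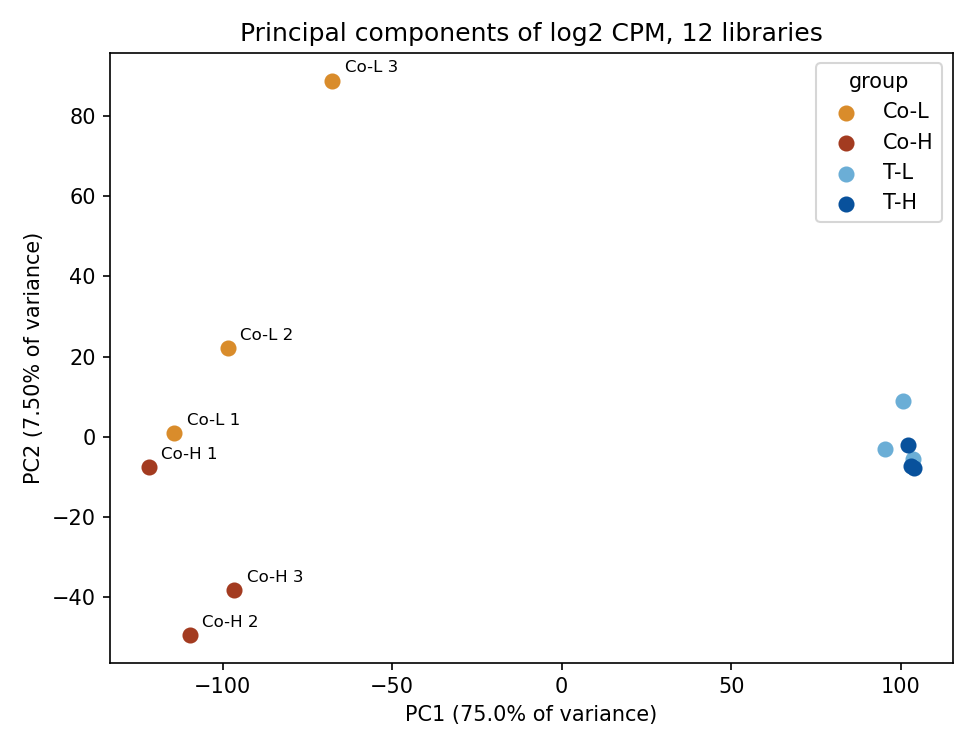
Principal components of log2 CPM over the 14839 tested genes, with PC1 on the x axis and PC2 on the y axis. Each point is 1 library, coloured by group. The first axis (75.0% of the variance) separates Co from T, and Co-L 3 lies apart from the other Co libraries on the second (7.50%).

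The first comparison asked which genes differed between the T and the Co tissue, averaged over fertility. Expression differed for 9553 of the 14839 genes (64.4%), 4700 higher and 4853 lower in T (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Genes called at 8-fold or more numbered 936 on the T side and 493 on the Co side, hereafter the T-biased and the Co-biased genes. Of the T-biased genes 41 had no counts in Co, and all 41 exceeded 8-fold against a floor of 3 counts over the 6 Co libraries. Of the Co-biased genes 12 had no counts in T, and all 12 exceeded 8-fold against the floor of T. The groups of libraries did not overlap for 40.2% of the genes, where chance gives 0.216%.

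The Co-biased genes took 10.6% ± 1.70 of the counts in Co and 0.496% ± 0.0386 in T (SD, n = 6 each). Their share was 7.83% in Co-L 3 and 9.24% to 11.8% in the other 5 Co libraries. The T-biased genes took 8.23% ± 4.05 in T and 0.193% ± 0.0906 in Co. Their share was 16.4% in T-H 1 and 5.71% to 6.96% in the other 5 T libraries, and in Co it was highest in Co-L 3, at 0.364%, with 0.114% to 0.217% in the others. These classes were drawn from the same libraries, so their shares describe the contrast and are no independent test of it.

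**Figure D2:**
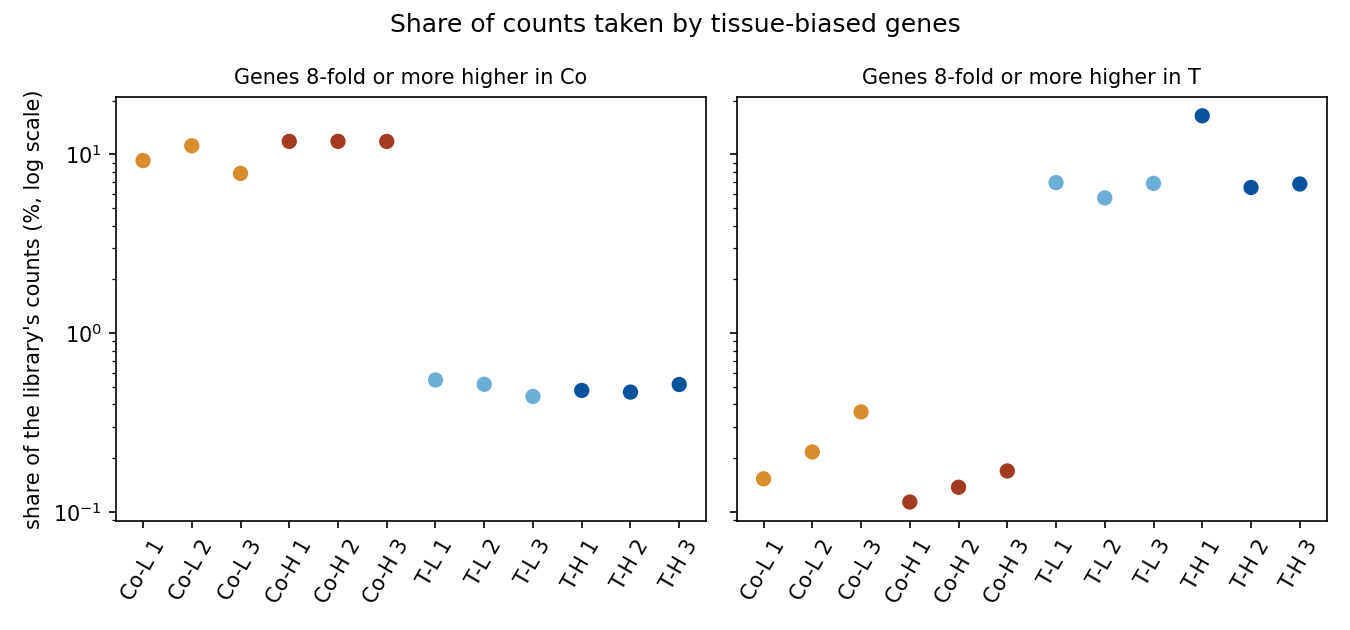
Share of each library's counts, in percent on a log axis, taken by the 493 genes at least 8-fold higher in Co (left) and the 936 at least 8-fold higher in T (right). Each point is 1 library, coloured by group. T-H 1 gives 16.4% of its counts to the T-biased genes, and Co-L 3 gives 0.364%, the highest of the Co libraries.

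The 2 genes with the greatest rise in T had no counts in any Co library. ENSBTAG00000021059 stood at 60.2 ± 16.7 CPM in T (SD, n = 6), at least 1581-fold higher than in Co against 3 counts over the 6 Co libraries (adjusted p = 3.4e-07). ENSBTAG00000045677 stood at 50.4 ± 30.5 CPM in T, at least 1322-fold higher on the same floor (adjusted p = 2.8e-06). The 2 genes with the greatest fall in T were abundant in Co. ENSBTAG00000006769 stood at 6564 ± 2276 CPM in Co and 0.229 ± 0.190 CPM in T, a log2 change of −14.66 (SE 0.48, adjusted p = 2.4e-09). ENSBTAG00000015902 stood at 1842 ± 573 CPM in Co and 0.277 ± 0.409 CPM in T, a log2 change of −13.34 (SE 0.53, adjusted p = 6.8e-09). All 6 libraries of one tissue lay above all 6 of the other for these 4 genes, which the rule for naming them required. The adjusted p-values are from the edgeR test.

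The second comparison asked which genes differed between high and low fertility in the Co tissue. In Co-H 365 genes were higher and 344 lower than in Co-L, 709 of 14839 in all (4.78%, edgeR, adjusted p under 0.05). Of the called genes 248 were higher by at least 2-fold and 114 lower by at least 2-fold, with 23 and 11 past 8-fold. The unadjusted p was under 0.05 for 4272 genes, against 742 expected by chance. Every Co-H library lay above or every Co-H library below all Co-L libraries for 23.1% of the genes, where chance gives 10%.

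ENSBTAG00000006541 rose from 0.955 ± 0.407 CPM in Co-L to 25.5 ± 20.9 CPM in Co-H (SD, n = 3 each), a log2 change of 4.70 (SE 0.93, edgeR adjusted p = 0.0463). ENSBTAG00000006790 rose from 1.87 ± 0.490 to 44.0 ± 35.6 CPM, a log2 change of 4.54 (SE 0.91, edgeR adjusted p = 0.0463). Both were at 37.5 CPM or more in Co-H 2 and Co-H 3, while Co-H 1 stood at 1.40 and 2.89 CPM, close to the Co-L libraries. In T their group means were between 0.802 and 1.14 CPM. ENSBTAG00000004129 fell from 7.69 ± 10.9 to 0.289 ± 0.179 CPM, a log2 change of −4.73 (SE 1.19, edgeR adjusted p = 0.0482). ENSBTAG00000039509 fell from 5.67 ± 8.24 to 0.234 ± 0.12 CPM, a log2 change of −4.58 (SE 1.17, edgeR adjusted p = 0.0490). Their Co-L means rested mainly on Co-L 3, at 20.3 and 15.2 CPM, with 0.528 to 2.28 CPM in Co-L 1 and Co-L 2. Without Co-L 3 their log2 changes were −2.24 and −1.91, and neither was called (edgeR adjusted p = 0.156 and 0.148). For all 4 genes the 3 libraries of one group lay above the 3 of the other, which the rule for naming them required.

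**Figure D3:**
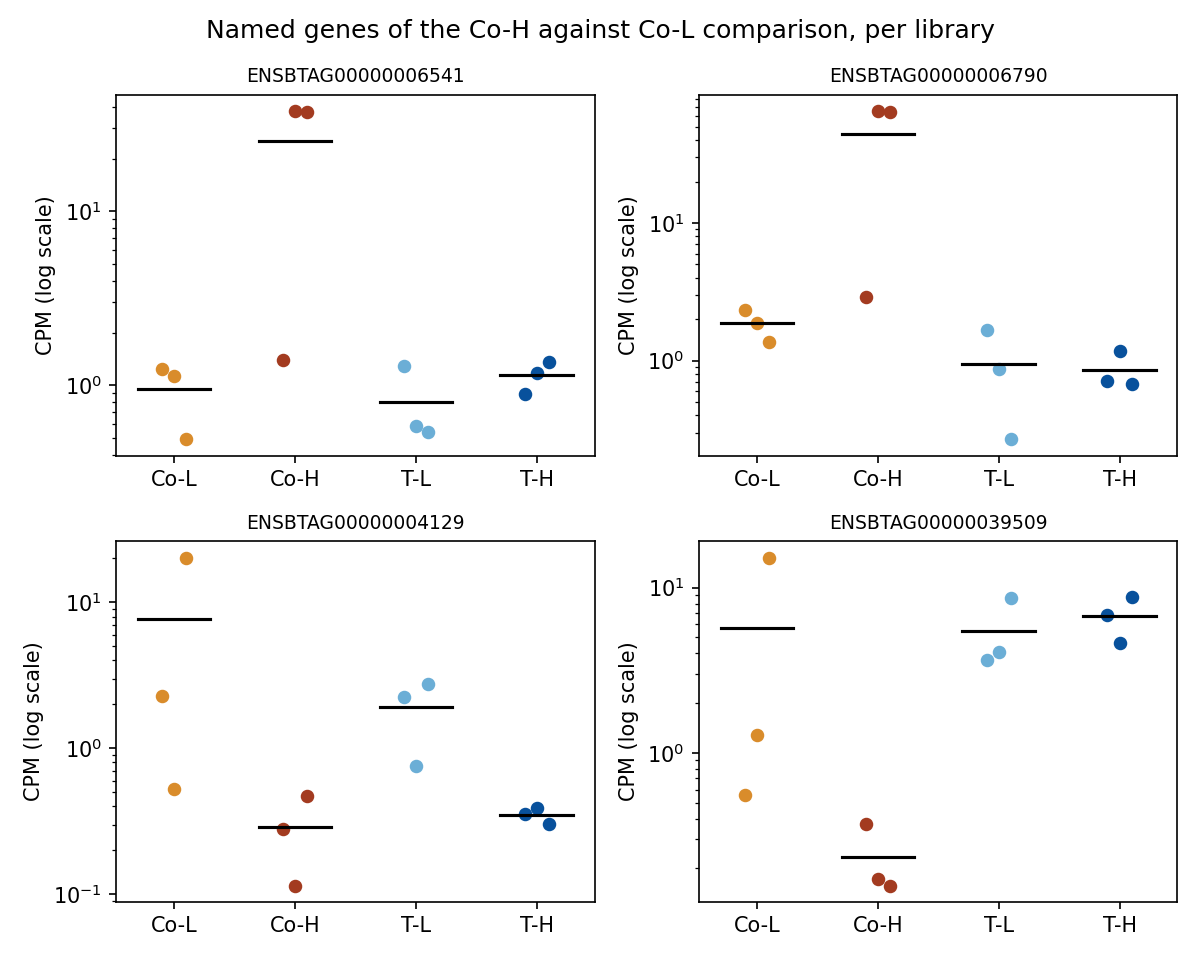
CPM on a log axis in each of the 12 libraries for the 4 genes named for Co-H against Co-L, by group on the x axis. Points are libraries, in order of replicate number within a group, and black lines are group means. Co-H 1 lies near the Co-L libraries for the 2 genes in the upper panels (1.40 and 2.89 CPM), and Co-L 3 is the highest Co-L library for the 2 in the lower panels (20.3 and 15.2 CPM).

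The T-biased genes stood lower in Co-H than in Co-L, with a median log2 change of −0.63 against −0.07 for all genes. Of these 936 genes 1 was called higher and 15 lower. Over the 765 of them with more than 3 counts in at least 1 group, with the 42 that were at 0 in a single group set to their bound, the median was −0.78. In camera, a test of a gene set against all other genes, the T-biased genes were lower at a preset correlation (adjusted p = 0.00128), a call lost with an estimated correlation (adjusted p = 0.431). The median was 0 without Co-L 3, −0.42 without Co-L 2 and −1.06 without Co-H 3. The Co-biased genes had a median of 0.00, with 6 called higher and 5 lower, and did not pass in camera (adjusted p = 0.125 preset, 0.431 with an estimated correlation).

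The 709 calls sat just under the threshold. The smallest adjusted p was 0.0292, the next 0.0463 and the highest among the called genes 0.0498. Without Co-H 1 the edgeR count was 3110 (1961 higher and 1149 lower) and without Co-L 1 it was 1131 (463 higher and 668 lower). It was 7 without Co-L 2, 2 without T-L 1, 1 without Co-L 3, and 0 without any of Co-H 2, Co-H 3, T-L 2, T-L 3, T-H 1, T-H 2 and T-H 3. Where a T library was left out and the count was 0, the smallest edgeR adjusted p was 0.0602 to 0.0716. The unadjusted p was then under 0.05 for 4035 to 4275 genes, against 4272 with all libraries. Without Co-H 2 and without Co-H 3 it was so for 2550 and 2904 genes, with a smallest edgeR adjusted p of 0.214 and 0.172. With only the 6 Co libraries in the fit 1 gene was called and without a count filter 3, while DESeq2 called 2258 genes and limma-voom with quality weights 4543. Without both Co-H 1 and Co-L 3, a setting chosen after the data were seen, 2664 genes were called (1802 higher and 862 lower).

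**Figure D4:**
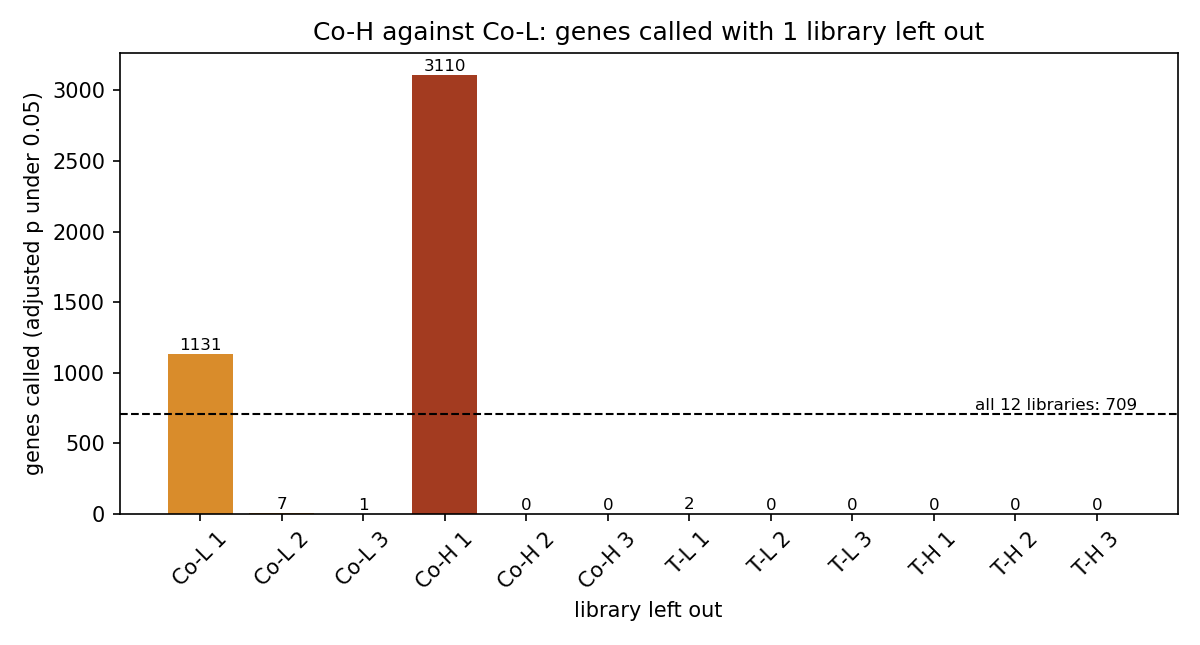
Genes called between Co-H and Co-L (edgeR, adjusted p under 0.05) with each of the 12 libraries left out in turn, named on the x axis, with bars coloured by the group of that library. The dashed line marks the 709 genes called with all libraries. Counts run from 0 to 3110, the highest without Co-H 1.

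The same comparison in the T tissue called 0 of 14839 genes (edgeR, smallest adjusted p = 0.356). The unadjusted p was under 0.05 for 608 genes, against 742 expected by chance, and the groups did not overlap for 10.4% of the genes, where chance gives 10%. DESeq2 called 26 genes, limma-voom with quality weights 3 and edgeR on the 6 T libraries alone 1, and the count was 0 with each of the 12 libraries left out. In simulated data with the spread of these libraries, 91.5% of genes changed 4-fold and 30% of those changed 2-fold were recovered in this comparison. These rates cover genes above a set mean count, not genes with few counts. T-H 1 differed from the other T libraries in the share of its top genes and of the T-biased genes given above.

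The genes with the smallest p in each direction did not pass in T. ENSBTAG00000009841 stood at 223 ± 37.2 CPM in T-L and 400 ± 59.7 CPM in T-H (SD, n = 3 each), a log2 difference of 0.84 (SE 0.15, edgeR adjusted p = 0.356). ENSBTAG00000003632 stood at 315 ± 111 and 758 ± 75.1 CPM, a log2 difference of 1.27 (SE 0.24, edgeR adjusted p = 0.362). ENSBTAG00000020406 stood at 4.96 ± 1.15 and 1.03 ± 0.238 CPM, a log2 difference of −2.23 (SE 0.36, edgeR adjusted p = 0.356). ENSBTAG00000008900 stood at 3.67 ± 0.288 and 0.951 ± 0.111 CPM, a log2 difference of −1.94 (SE 0.31, edgeR adjusted p = 0.356). All 3 T-H libraries lay on one side of all 3 T-L libraries for each of the 4. The medians of the T-biased and Co-biased genes were −0.01 and −0.06, with 0 genes called in either class.

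Averaged over both tissues, 3 genes differed between high and low fertility, 1 higher and 2 lower (edgeR, adjusted p = 0.0449 for each). ENSBTAG00000011985 was higher in high fertility by a log2 change of 3.03 (SE 0.38), at 1.34 ± 0.462 CPM in Co-L and 24.4 ± 5.60 in Co-H, and at 5.50 ± 4.55 in T-L and 20.2 ± 7.58 in T-H (SD, n = 3 each). ENSBTAG00000021211 was lower by a log2 change of −1.45 (SE 0.19), at 263 ± 92.4 CPM in Co-L and 66.2 ± 15.9 in Co-H, and at 23.9 ± 2.31 in T-L and 12.7 ± 2.87 in T-H. ENSBTAG00000038540 was lower by a log2 change of −0.94 (SE 0.12), at 25.2 ± 2.29 CPM in Co-L and 11.6 ± 1.01 in Co-H, and at 12.2 ± 0.601 in T-L and 7.16 ± 1.56 in T-H. For each of these 3 genes the high and low libraries did not overlap within either tissue. The next gene in the upward direction, ENSBTAG00000015896, did not pass (log2 difference 0.65, SE 0.12, edgeR adjusted p = 0.140). The unadjusted p was under 0.05 for 2853 genes, against 742 expected by chance and up to 3302 in other splits of the libraries. The split with 3302 kept the real groups in Co and regrouped only T. Among the drawn splits that regrouped Co the highest gave 2588.

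The count over both tissues also turned on single libraries. It was 1495 without Co-H 1, 5 without Co-L 1, 1 without each of Co-L 3, Co-H 3 and T-L 1, and 0 without any of Co-L 2, Co-H 2, T-L 2, T-L 3, T-H 1 and T-H 3. DESeq2 called 559 genes and limma-voom with quality weights 2212.

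Whether fertility acted differently in the tissues was tested as the difference between the T and the Co contrast. It called 0 of 14839 genes (edgeR, smallest adjusted p = 0.257). The unadjusted p was under 0.05 for 2423 genes, against 742 expected by chance and up to 2862 in other splits of the libraries. The split with 2862 kept the real groups in Co and regrouped only T. DESeq2 called 131 genes and limma-voom with quality weights 1675, and edgeR without Co-H 1 called 1237, against 0 without each of the other 11 libraries. A call in Co without one in T therefore does not show a difference between the tissues. ENSBTAG00000014354 stood at 153 ± 5.17 CPM in Co-L and 76.4 ± 6.66 in Co-H, where it fell (log2 change −1.0, SE 0.11, edgeR adjusted p = 0.0292), and at 53.2 ± 4.22 in T-L and 52.9 ± 3.89 in T-H. Its difference between tissues was 0.996 (SE 0.16, edgeR adjusted p = 0.257). ENSBTAG00000012377 stood at 13.6 ± 3.27 CPM in Co-L and 35.4 ± 10.8 in Co-H, and at 38.1 ± 0.529 in T-L and 29.9 ± 2.59 in T-H. Its difference between tissues was −1.73 (SE 0.32, edgeR adjusted p = 0.257).

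The fertility contrasts of the tissues share no libraries. Across the 14839 genes, which are not independent replicates, their log2 changes had a Pearson's r of 0.0061 and a Spearman's rho of 0.078. Of the 709 genes called in Co 449 (63.3%) had the same sign in T, against 53.0% of all genes. The share was 56.5% among the genes called without Co-H 1. These shares were chosen after the data were seen. High and low libraries were fully separated in the same direction in both tissues for 207 genes (1.40%) and in opposite directions for 146 (0.984%), with 178 and 177 expected if the tissues were unrelated, given the genes separated in each.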

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

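The tests of chance by other splits within Co and within T were chosen after those results were seen, and the numbers of splits drawn for the other comparisons were settled after smaller draws had been seen. A check for single libraries far from their group was not applied, since the groups hold 3 libraries each.

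Of the genes named for any comparison, 4 had every high-fertility library on one side of the low-fertility libraries in Co and on the opposite side in T. ENSBTAG00000009841 differed between the tissues by 1.07 on the log2 scale (SE 0.22), with a high-minus-low value of −0.22 in Co and 0.84 in T. ENSBTAG00000008966 differed by 1.27 (SE 0.23), with −0.86 in Co and 0.40 in T. ENSBTAG00000020141 differed by −3.18 (SE 0.57), with 0.78 in Co and −2.40 in T, where it had 10 counts over the 3 T-H libraries. ENSBTAG00000012377 differed by −1.73 (SE 0.32), with 1.38 in Co and −0.35 in T. ENSBTAG00000008966, ENSBTAG00000020141 and ENSBTAG00000012377 were named for a small p of this difference, so opposite directions in them follow in part from how they were picked. The difference itself was tested in edgeR and did not pass for any of the 4 genes (adjusted p = 0.257 for each). Opposite directions of this kind were seen in 146 of 14839 genes, with 177 expected if the tissues were unrelated, given the genes separated in each.

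For the difference between tissues as a whole, the real count is 0, which all 100 drawn splits must reach, with 3 in the highest of the others, so that count says nothing. By genes at an unadjusted p under 0.05 6 of the 100 splits, the real one with 2423 included, gave as many, a share not under 0.05, so chance was not excluded. The others of these 6 kept the real groups in Co or, in 1 split with 2588, only exchanged Co-L 1 with Co-H 1 there. This share therefore does not measure chance for the Co part of the difference. For T-H against T-L the 10 possible splits are too few for a share under 0.05, with 0 genes in the real split, a count that all 10 must reach, and at most 1 in the others. For Co-H against Co-L 10 splits are likewise too few, with 709 genes in the real split and at most 27 in the others, and by genes at an unadjusted p under 0.05 with 4272 in the real split and up to 3453 in the others. For T against Co 1 of the 60 drawn splits, the real one, gave 9553 genes, so chance was excluded. The highest other split gave 2349 and differed from the real one only by exchanging Co-L 3 and T-L 3. For high against low over both tissues 2 of the 100 drawn splits, the real one included, gave 3 or more genes. The other one, also with 3 genes, kept the real groups in Co and regrouped the T libraries. That share is under 0.05, but 100 of the 200 possible splits were not run, a smaller earlier draw held a split with more genes than the real one, and the count falls to 0 when any 1 of 6 libraries is left out, so chance is not taken as excluded for these 3 genes.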

How the results depend on the processing

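T against Co gave 9553 genes and 9080 to 10417 over all alternatives run, within 1.5 times of each other, and the share of calls higher in T was 48.9% to 55.0%. The other counts moved, and the cause was not tested beyond what each setting removes. Co-H against Co-L gave 709 genes in the edgeR fit, 2258 with DESeq2, 4543 with limma-voom and quality weights, 3 without a count filter and 1 with only the 6 Co libraries. RLE, upper-quartile scaling and the CPM filter gave 786, 727 and 807. T-H against T-L gave 0, and 26 with DESeq2, 3 with limma-voom and 1 with only the 6 T libraries. High against low over both gave 3, 559 with DESeq2 and 2212 with limma-voom. The difference between tissues gave 0, 131 with DESeq2 and 1675 with limma-voom. Leaving out each library in turn gave 0 to 3110 genes for Co-H against Co-L, 0 for T-H against T-L throughout, 0 to 1495 for high against low over both and 0 to 1237 for the difference between tissues, each highest without Co-H 1. Chosen after the data were seen, an adjusted p under 0.1 gave 2466 genes for Co-H against Co-L and 9 for high against low over both, and leaving out both Co-H 1 and Co-L 3 gave 2664 for Co-H against Co-L.

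Of 12 pairs of same-numbered libraries 3 had a correlation of deviations above 0.1, over a range of −0.287 to 0.249. Since this was not so for every pair, the numbers were not taken to pair the libraries, although 2 of the 3 low and high pairs in Co were among them (0.213 and 0.249). With the replicate block, Co-H against Co-L gave 40 genes (4 higher and 36 lower, 10 of them among the 709), T-H against T-L 0, T against Co 9251, high against low over both 20 and the difference between tissues 17.

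The 20 gene results were refitted in 393 gene and setting combinations. The direction reversed in 0 of them, the call was lost in 85 and gained in 19. Of the losses 55 were in the genes named for Co-H against Co-L and 30 in those for high against low over both. The median log2 change of the T-biased genes between Co-H and Co-L was 0 to −1.06 with 1 Co library left out. The planned gene list tests gave no value under any setting, since no identifier could be named. Depth limits the genes at the floor of 3 counts. In simulated data most 2-fold changes between groups of 3 were missed, with 20% recovered in Co and 30% in T. Those changed genes were taken from genes above a set mean count.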

Other observations

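The tests in this part were chosen after the patterns were seen. The comparison with abundant T-biased genes for Co-L 3 was set before its own result, but for a set of genes already seen. Patterns and tests come from the same libraries, so the explanations are hypotheses.

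Some genes were found in a single tissue. On CPM of the unadjusted library total, at 1 CPM or more in all 6 libraries of a tissue and under 0.1 CPM in all 6 of the other, 53 genes were specific to T and 15 to Co in these libraries. For each library, genes higher in T or in Co were also picked anew from the other 11 libraries, by mean log2 CPM at 8-fold or more and without a test. For the Co libraries this gave 730 to 832 genes higher in T and 388 to 417 higher in Co. Against the mean of the other libraries of its tissue, the median gene of the first kind was 0.96 higher on the log2 scale in Co-L 3. It was between −0.53 and 0.14 in the other 5 Co libraries. The median gene of the second kind was −0.40 in Co-L 3 and between −0.09 and 0.14 in the others.

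In Co-L 3 237 genes, with 1.56% of its counts, stood at least 4-fold above every other Co library and at 2 CPM or more. ENSBTAG00000033545, picked after its values were seen, had 1363 CPM there and at most 0.415 CPM in the other Co libraries. In T-H 1 126 genes, with 7.46% of its counts, stood alone in the same way, against 1 to 10 genes in each of the other 10 libraries. The sets shared 4 genes, with 2.01 expected by chance (Fisher's exact test, one-sided p = 0.143).

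For both sets the tables argue against depth, since 229 and 125 such genes were left when all libraries were thinned to the smallest total. They argue against admixture of the other tissue as the only source of either set. Above every T library stood 51.5% of the Co-L 3 genes, and above every Co library 93.7% of the T-H 1 genes. For the 99 Co-L 3 genes that were T-biased, T tissue would bring all abundant T-biased genes at a similar share. The 50 most abundant reached a median of 0.795% of their T level, against a lower quartile of 15.4% for the 99. The 99 were picked for being high in Co-L 3, which raises their share, and all 936 T-biased genes had a median of 2.26%. A small admixture of T tissue in Co-L 3 therefore stays open, by these medians at too low a share to bring the 99 to their levels. RNA of a tissue or cell type not sampled here, or a difference between the animals, may be the source, and neither was tested.

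Co-H 1 lay nearest to a low-fertility library, with a Pearson's r across genes of 0.982 with Co-L 1 and at most 0.965 with its own group, while Co-H 2 and Co-H 3 were nearest to each other (r = 0.981). The nearness was mutual, since Co-L 1 also lay nearest to Co-H 1. Co-L 2 lay nearest to Co-H 1 as well, by a small margin (r = 0.9701, against 0.9696 in its own group). In T, T-L 2, T-L 3 and T-H 3 were nearest to a library of the other fertility level. The tables argue against depth, since after thinning r was still 0.980 with Co-L 1 and at most 0.963 with its own group. Each Co library was also placed on an axis of its own, set by the other Co libraries, from 0 for low to 1 for high. Co-H 1 lay at 0.164, the Co-L libraries at 0.0545 to 0.721 (SD 0.334), Co-H 2 at 1.30 and Co-H 3 at 0.908. The highest of the Co-L libraries was Co-L 1. These axes differ in genes, with 3028 for Co-H 1 and 1074 to 2163 for the Co-L libraries. The Co-L axes also count Co-H 1 as high, so the positions are not on one scale. The axes were built after Co-H 1 was seen nearest to Co-L 1, so its position adds no separate test of its label. A low-fertility sample under the label of Co-H 1 stays open, as does a high-fertility sample under the label of Co-L 1. A true difference among the high-fertility samples, or one in library composition, also stays open and was not tested. Exchanging Co-H 1 with Co-L 1, Co-L 2 or Co-L 3 gave 0, 1 and 16 called genes and 3453, 2419 and 2795 genes at an unadjusted p under 0.05, against 709 and 4272 under the labels as given. Each exchange also put a Co-L library into the high group. These counts therefore do not test a wrong label of Co-H 1 alone, a regrouping that was not run. Leaving out Co-H 1 gave 3110 called genes.

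In both tissues 10 genes were on in some libraries and off in others, at 2 CPM or more or at 0.5 CPM or less of the unadjusted library total in each of the 12, and they fell into 6 patterns over the libraries. The states of same-numbered Co and T libraries matched in 45% of 60 combinations, and of 36 ways of pairing the libraries within fertility levels 28, this one included, matched at least as well, up to 61.7%. Since no pairing came near a full match, and it is not known whether such a state is a fixed trait of an animal, these genes do not tell whether same-numbered libraries came from the same animals. A sequence difference between animals and the cattle reference may switch such genes off, which was not tested.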
